A study of Mus musculus with 149 samples.

How the data were processed

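Single-cell RNA sequencing was done on AB17 cells, a mouse line made from primary hepatocytes of C57BL/6 mice with loxP-flanked Arid1a alleles, immortalized with SV40 large T antigen and then transformed with mutant Hras, each delivered by lentivirus, per the labels' protocols. The cells received an adenovirus carrying GFP (Ad-GFP) or an adenovirus carrying Cre recombinase (Ad-Cre), and GFP-positive cells were sorted 48 h later. Cells were captured on the Fluidigm C1 instrument with the chip for cells of 10 to 17 µm, their RNA was amplified with the SMARTer chemistry together with ERCC spike-in RNA, and Nextera XT libraries were read as 150 bp pairs, per the labels' protocols. This chemistry covers whole transcripts, carries no molecular identifiers and does not mark the strand, so reads from overlapping or antisense genes cannot be told apart.

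The deposited table holds raw counts per gene and per spike-in for each cell, as whole numbers with no normalization. The submitters' processing notes name Trimmomatic 0.36, TopHat2 2.1.0, HTSeq 0.8.0 and the genome build GRCm38, without roles or parameters. The annotation, the counting mode and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies, such as the class I genes H2-K1, H2-K2 and H2-Q4, Ly6c1 and Ly6a, Serpinb1a and Gstm1, are therefore uncertain. So are named genes that overlap another gene on the other strand, among them Cnbd2, Zfp296, Bex1, Phf10, Shmt2, Cryab, Cd274, Hk2, Hmgcs1, Cd34, E2f8, Hmga2, Ezr and Medag. The table has 24451 gene rows, of which 17963 had a count in any cell, and 92 spike-in rows. In 27 gene rows, with 0.280% of the gene counts, the symbol had been turned into a date, and these rows stayed in the totals and were not named. Of the gene symbols, 23401 (95.7%) occur in the GENCODE M21 annotation, from which the GRCm38 coordinates were taken. No symbol carried the mitochondrial prefix, so no mitochondrial share was computed.

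Each column was matched to a cell by its title, and the group was taken from the description of each cell. The stated 73 Ad-GFP and 76 Ad-Cre cells were all present. All of them passed the filter of at least 100000 gene counts and at least 2000 genes with a count. The columns held 0 identical pairs, and the highest Pearson r of log2 counts between any 2 cells was 0.821. No doublet caller was run, so capture sites that held more than 1 cell were not removed. Every GEO sample is 1 cell and the labels name no separate cultures, so each infection was treated as 1 sample. The titles carry a different prefix for each infection. The labels do not say whether a prefix stands for 1 capture chip, but any batch that follows it coincides fully with the infection. No p-value, standard error or count of changed genes was therefore made from cells. Cells with title letters A to D and E to H were compared apart as a check within each infection.

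Gene counts were summed over the cells of an infection and expressed as CPM, the count per 1000000 gene counts, with exact Poisson 95% intervals. Folds carry the exact conditional interval of a ratio of 2 Poisson rates. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals. PCR reads without molecular identifiers are not independent molecules, so the Poisson-based intervals can be too narrow even for counting error. They leave out the spread between cells, and none of the intervals covers the spread between cultures. A gene with a sum of 0 in an infection was set to 3 counts, which gives a bound on the fold, and the 2-sided exact limit, which is wider, is given beside it. The spread over cells is given as the SD of log2(CPM + 1). Shares of cells with a count and genes per cell were compared after thinning each cell to 1000000 gene counts, which left out 2 Ad-GFP and 8 Ad-Cre cells.

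Gene lists and naming rules were fixed before the data were examined. A list was described by the median log2 ratio (Ad-Cre over Ad-GFP) of its members with at least 5 CPM in either infection, and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. Of 31 lists, 27 had the required 5 members. Named genes were Arid1a, the 12 highest and the 12 lowest ratios among genes with at least 20 CPM in either infection and a count in at least 30% of the cells of the higher infection, and, with the same minimum of 20 CPM, the 3 members of each list with the largest absolute log2 ratios. The sign had to agree in the mean of log2(CPM + 1), among cells A to D and among cells E to H. For the genes it selected, this rule fixed the sign in the mean of log2(CPM + 1). It also favoured agreement in both sets of cells, so such agreement is no separate check. Predicted genes with Gm or Rik symbols were not named. The member of each list closest to 0 among those with at least 100 CPM could be named as an example of a small difference. Members named because few went against the rest of a list, and Alb, were chosen after their values were seen.

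The main axis of the cells was the first diffusion component (scanpy 1.11.5, 15 neighbours, 20 principal components) over the 1000 genes with the highest variance of log2(CPM + 1) above the trend with the mean, among genes with at least 5 CPM in either infection. The end with the lower mature hepatocyte score was taken as the far end. Clusters came from Ward clustering (scikit-learn 1.9.0) on the 20 principal components, with 2 to 8 clusters tried and the number chosen by the highest mean silhouette. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and R 4.3.3 were used. The procedure was tested on simulated counts drawn from the real means and library sizes over 9945 genes, with the same assumed variance between cells for every gene. For the Ad-Cre against Ad-GFP ratio, 100 genes simulated at a log2 fold of 1 were recovered at a median of 0.96 (SD 0.34), with the right sign in 99%. Another 100 genes at a log2 fold of 2 came out at a median of 2.04 (SD 0.41), with the right sign in 100%. The axis was tested in 2 simulated Ad-Cre against Ad-GFP settings over the same 9945 genes. With those 200 changed genes it placed the simulated Ad-Cre cell further along in only 72.9% of cell pairs. A larger difference, 1000 genes at a log2 fold of 1.5, was then simulated, and the share was 100%. In these simulations the axis therefore recovered a difference in many genes and could miss one in few. Simulated genes varied independently of each other, unlike those of real cells, and their variance was not fitted to these cells. Neither the recovery of the folds nor the shares need therefore carry over.

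Alternatives planned ahead were no cell filter, a stricter cell filter (500000 counts and 4000 genes), the mean of per-cell CPM, the difference of mean log2(CPM + 1), edgeR 4.0.16 TMM factors and DESeq2 1.42.0 size factors on the 2 sums, scaling to the spike-in total, other filters on low values, each set of title letters alone, omission of the 5 deepest cells of each infection, other depths of thinning, other gene numbers, omission of the cell cycle genes or the first principal component for the axis, each infection clustered alone, and other numbers of clusters. Chosen after seeing the data were omission of cells with a spike-in share above 10%, restriction to cells with 6000 to 8000 genes with a count, and omission of the single cell with the highest Arid1a CPM in each infection.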

Results

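The series asked how the transcriptome of transformed mouse hepatocytes lies along a dedifferentiation path once Arid1a, the DNA-binding subunit of a SWI/SNF chromatin remodelling complex, is removed. Full-length transcriptomes of single AB17 cells were compared, 73 after infection with Ad-GFP, the control virus, and 76 after infection with Ad-Cre, which deletes loxP-flanked Arid1a. The median cell had 3764720 gene counts in Ad-GFP (range 585021 to 5068530) and 3338352.5 in Ad-Cre (range 126523 to 6090117). The summed counts were 266735056 and 251869341. The labels name no replicate cultures, capture chips or dates, so each infection was treated as 1 sample and the differences below have no replicate check. The cell titles carry 1 prefix per infection, so a batch that follows the prefix would coincide with the infection. Fold intervals treat reads as independent counts and leave out the spread between cells and between cultures.

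Arid1a RNA was lower in Ad-Cre cells. Arid1a (chromosome 4, 133679008 to 133756769, GRCm38, minus strand) stood at 45.97 CPM in Ad-GFP (45.2 to 46.8) and 31.3 CPM in Ad-Cre (30.6 to 32.02), which is 1.47-fold lower (1.43 to 1.51). The mean of log2(CPM + 1) over cells was 4.41 ± 2.33 (SD, 73 cells) in Ad-GFP and 2.97 ± 2.77 (SD, 76 cells) in Ad-Cre, a larger difference of -1.44. The median cell had 30.8 CPM in Ad-GFP and 8.33 CPM in Ad-Cre. No Arid1a count was found in 8 of 73 Ad-GFP cells and 26 of 76 Ad-Cre cells. After thinning, 84.5% of Ad-GFP cells (73.97% to 92.0%) and 61.8% of Ad-Cre cells (49.2% to 73.3%) had a count, against 89.0% and 65.8% before thinning. The highest single cell had 230.1 CPM in Ad-GFP and 708.5 CPM in Ad-Cre. Both were cells of low yield, with 3684 and 3311 genes with a count and spike-in shares of 32.4% and 21.2%. Counts per gene include exons that a conditional deletion leaves in place, so these values do not give the share of cells with a deleted allele.

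Of 23 measured SWI/SNF subunits, a list that includes Arid1a, 16 were higher in Ad-Cre and 7 lower, with a median log2 ratio of 0.51 at percentile 94.9, inside the range of the random lists. Phf10, a PBAF subunit, was 3.32-fold higher (3.28 to 3.36), Bcl7b 2.44-fold higher (2.39 to 2.498) and Brd7, another PBAF subunit, 2.36-fold higher (2.32 to 2.41). Smarca4, the BRG1 ATPase, was at 107.5 and 123.7 CPM, a log2 ratio of 0.20.

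**Figure D1:**
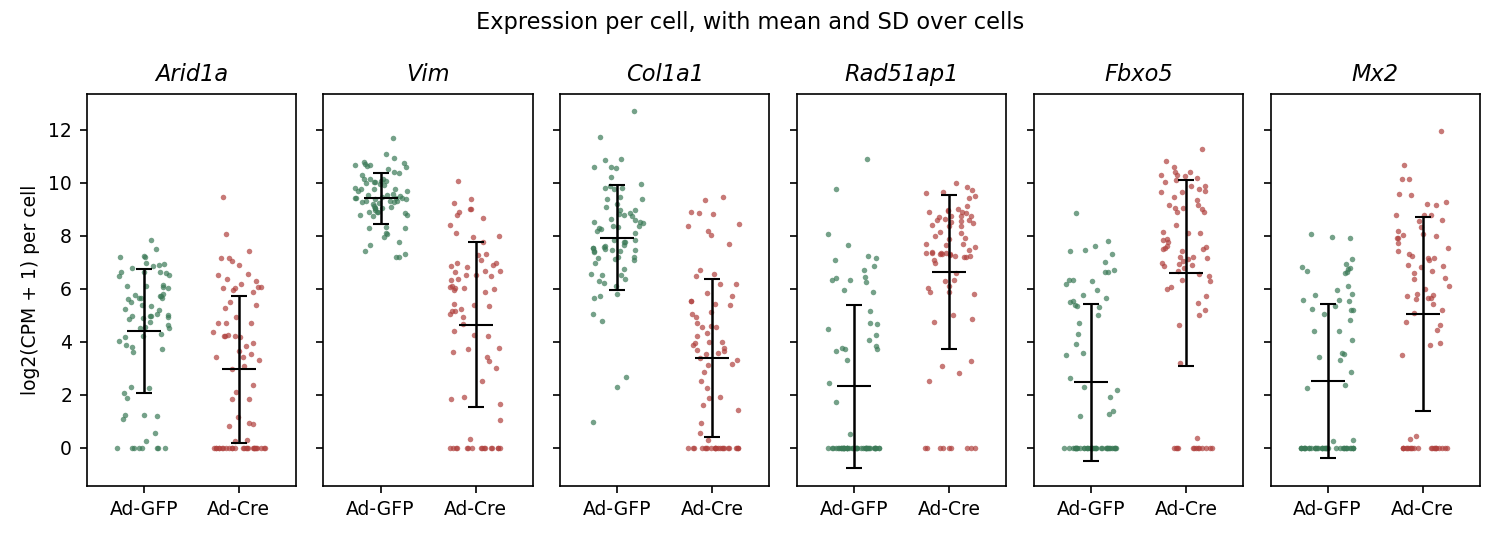
Log2(CPM + 1) of 6 genes in each cell (points), with the mean and SD over cells (black), for Ad-GFP (73 cells) and Ad-Cre (76 cells). Vim and Col1a1 have lower means in Ad-Cre, Rad51ap1, Fbxo5 and Mx2 higher ones, and Arid1a means are 4.41 and 2.97.

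The 12 genes with the highest Ad-Cre to Ad-GFP ratios were between 10.3-fold and 2428-fold higher in Ad-Cre. Fbxo5 (Emi1, an inhibitor of the anaphase-promoting complex; chromosome 10, 5799160 to 5805600) was at 32.6 CPM in Ad-GFP and 335.9 CPM in Ad-Cre, 10.3-fold higher (10.1 to 10.5). Its mean log2(CPM + 1) was 2.48 ± 2.96 and 6.59 ± 3.52 (SD over 73 and 76 cells). Ifit2, an interferon-induced antiviral gene, was 11.3-fold higher (11.1 to 11.5), at 533.8 CPM in Ad-Cre. Lrr1, a substrate receptor of a CUL2 ubiquitin ligase, was 11.5-fold higher (10.9 to 12.2). Nrip3 (chromosome 7, 109758055 to 109782025) had 4 counts in Ad-GFP and 9169 in Ad-Cre, 2428-fold higher (948 to 8911). Before thinning 1.37% of Ad-GFP and 32.9% of Ad-Cre cells had a Nrip3 count, and after thinning 32.4% of Ad-Cre cells (21.5% to 44.8%) had a count against 0 of 71 Ad-GFP cells, for which the binomial upper limit is 5.06%. Cd209c, a C-type lectin gene, was 38.8-fold higher (34.7 to 43.7) and Zfp296, a zinc finger gene, 20.5-fold higher (18.4 to 22.96). The neighbouring X-linked genes Bex2 and Bex1 were 16.2-fold (15.3 to 17.2) and 15.9-fold (14.6 to 17.4) higher, and the atypical chemokine receptor gene Ccrl2 was 11.3-fold higher (10.5 to 12.1). Cnbd2 was 35.02-fold higher (30.1 to 40.98), Dbhos, annotated as an antisense transcript, 23.9-fold higher (21.6 to 26.5), and H2-K2, an annotated pseudogene, was at 1.34 and 36.2 CPM. Cnbd2 overlaps Scand1, Zfp296 overlaps Gemin7 and Bex1 overlaps Tceal7 on the other strand, and H2-K2 is a near copy of other class I genes, so these values are uncertain.

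The 12 genes with the lowest ratios were at least 22.6-fold lower in Ad-Cre. Spp1 (osteopontin; chromosome 5, 104435118 to 104441050) was at 1298 CPM in Ad-GFP and 3.52 CPM in Ad-Cre, 369-fold lower (345 to 394), and 76.1% of thinned Ad-GFP cells (64.5% to 85.4%) and 8.82% of thinned Ad-Cre cells (3.31% to 18.2%) had a Spp1 count, against 80.8% and 7.89% before thinning. Lcn2, an acute-phase lipocalin, had 30588 counts in Ad-GFP and 3 in Ad-Cre. Its fold was 9628-fold lower with a counting interval of 3294 to 46689. Spon2, a secreted matrix protein, had 18507 counts against 0 and was at least 5825-fold lower with the 0 set to 3 counts over the group, where the exact interval starts at 4737. The collagenase Mmp13 was 533-fold lower (385 to 762) and the stromelysin Mmp10 25.9-fold lower (23.7 to 28.3). The neutrophil chemokine Cxcl5 was 42.6-fold lower and Enpp2, which encodes autotaxin, 32.6-fold lower (30.7 to 34.6). Medag was 56.2-fold, the guanine deaminase gene Gda 50.8-fold and the germ-cell helicase gene Ddx4 39.3-fold lower. Serpinb1a was at 62.7 and 2.73 CPM and Ly6c1 was 22.6-fold lower, and both have near-identical copies, so these values are uncertain. Several of these genes were uneven between cells of the same infection: Enpp2 had a count in 21.1% of thinned Ad-GFP cells and 16.2% of thinned Ad-Cre cells (31.5% and 15.8% before thinning).

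**Figure D2:**
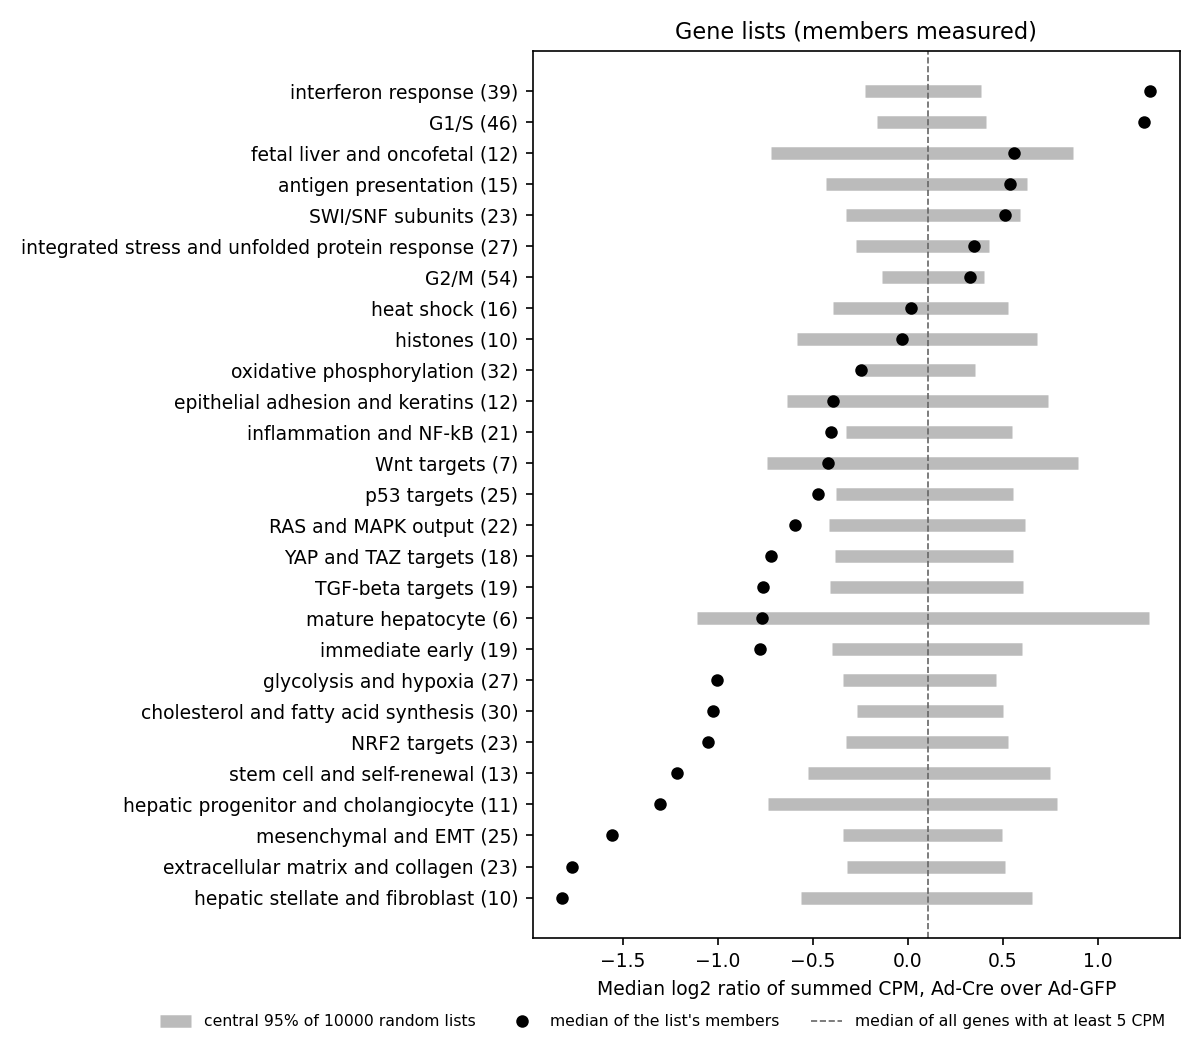
Median log2 ratio of summed CPM (Ad-Cre over Ad-GFP) of 27 gene lists, with the number of measured members in parentheses (dots), the central 95% of the medians of 10000 random lists matched on expression (grey bars) and the median of all genes with at least 5 CPM (dashed line, 0.11). Interferon response and G1/S lie above their bars, and 14 lists lie below theirs.

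Genes of the G1/S list, many of them replication factors, were higher in Ad-Cre. Of 46 measured members 44 were higher, with a median log2 ratio of 1.25, above 100% of the random lists. E2f8, a transcription factor of the E2F family, was 8.87-fold higher (8.49 to 9.27), Rad51ap1 7.24-fold higher (7.08 to 7.40), and Dtl, which directs licensing factors to degradation, 5.90-fold higher (5.75 to 6.05). As the mean of per-cell CPM, Rad51ap1 stood at 63.8 in Ad-GFP and 256.5 in Ad-Cre, a smaller ratio. After thinning, Rad51ap1 had a count in 39.4% of Ad-GFP cells (28.03% to 51.7%) and 89.7% of Ad-Cre cells (79.9% to 95.8%), against 42.5% and 88.2% before thinning. The other 2 members were Rrm1, a subunit of ribonucleotide reductase, with a log2 ratio of -0.04, and Mrpl36, with -0.47. The mean log2(CPM + 1) of Rrm1 was lower in Ad-Cre, 6.93 against 8.02 in Ad-GFP. Of 54 members of the G2/M list 38 were higher and 16 lower, and the median of 0.33 lay at percentile 92.1, inside the range of the random lists. Its median was larger as a difference of mean log2(CPM + 1), 0.79, and among cells with 6000 to 8000 genes with a count, 0.70. Both lay above random lists drawn the same way. From summed counts it was 0.20 with the stricter cell filter and, in cells E to H, 0.093 at percentile 51.6. As a difference of mean log2(CPM + 1) it was 0.71 in cells A to D and 0.99 in cells E to H. Top2a was 3.30-fold (3.24 to 3.35), Cenpf 2.96-fold (2.89 to 3.02) and Bub1 2.46-fold higher, while Cks1b was at 423.0 and 423.7 CPM.

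Interferon response genes were also higher in Ad-Cre, in 37 of 39 measured members, with a median log2 ratio of 1.28 above 100% of the random lists. The other 2 were Ifi27, with a log2 ratio of -0.23, and Zbp1, with -0.49. Among cells with 6000 to 8000 genes with a count the median was 0.75. Mx2, an interferon-induced gene annotated as a polymorphic pseudogene, was at 31.2 and 215.9 CPM, 6.93-fold higher (6.77 to 7.09). Ifnb1, the gene of interferon beta (chromosome 4, 88522025 to 88522774), had 0 counts in Ad-GFP and 12085 in Ad-Cre, at least 4266-fold higher with the 0 set to 3 counts over the group, where the exact interval starts at 3469, and the Ad-Cre counts came from few cells: 5 of 68 thinned Ad-Cre cells (7.35%, 2.43% to 16.3%) had a count, and 6.58% of all Ad-Cre cells before thinning. Bst2 had a count in every thinned cell, with a log2 ratio of 0.22. Antigen presentation genes had a median of 0.54 at percentile 94.4, inside the range of the random lists, with 11 of 15 members higher, but 0.95 with the mean of per-cell CPM, above that range. In that list Cd274, the gene of PD-L1, was at 8.57 and 64.2 CPM, a log2 ratio of 2.91, H2-K1 2.45-fold higher (2.42 to 2.47) and H2-Q4 5.09-fold higher (4.82 to 5.39), the last 2 with near-identical class I copies. As the mean of per-cell CPM, H2-Q4 stood at 5.93 in Ad-GFP and 62.5 in Ad-Cre, a larger ratio. In the integrated stress and unfolded protein response list, 19 of 27 members were higher (median 0.35, percentile 93.1, inside the range), with Shmt2 2.53-fold, Ddit3 2.495-fold (2.47 to 2.52) and Trib3 2.35-fold (2.30 to 2.41) higher. As a difference of mean log2(CPM + 1) the median of that list was -0.090 in cells A to D and 0.29 in cells E to H.

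Genes of the matrix and mesenchymal lists were lower in Ad-Cre. All 23 measured extracellular matrix and collagen genes were lower, with a median log2 ratio of -1.77, below every random list, and a median difference of mean log2(CPM + 1) of -2.80. The fibrillar collagen gene Col1a1 was 6.30-fold lower (6.20 to 6.40), Col5a1 5.96-fold lower (5.79 to 6.13) and the proteoglycan gene Bgn 5.72-fold lower (5.64 to 5.79). Of 25 mesenchymal genes 24 were lower (median -1.56, below every random list), and the other, Zeb1, was at 28.8 and 29.97 CPM with a lower mean log2(CPM + 1) in Ad-Cre. The intermediate filament gene Vim (chromosome 2, 13573927 to 13582826) was at 792.9 and 122.6 CPM, 6.47-fold lower (6.39 to 6.54), with a mean log2(CPM + 1) of 9.43 ± 0.97 in Ad-GFP and 4.65 ± 3.11 in Ad-Cre (SD over 73 and 76 cells). S100a4 was 9.64-fold lower (9.38 to 9.92). In the TGF-beta target list 15 of 19 members were lower (median -0.77), among them Ltbp1 (5.08-fold lower, 4.87 to 5.31) and Cdkn2b (3.58-fold lower, 3.49 to 3.67), while Skil, Tgfb1, Tgfb2 and Pmepa1 had higher sums, of which Tgfb1 alone also had a higher mean log2(CPM + 1). In the YAP and TAZ target list 11 of 18 were lower (median -0.72), with Cyr61 3.18-fold (3.15 to 3.21), F3 2.13-fold (2.11 to 2.14) and Axl 2.06-fold (2.03 to 2.095) lower. Immediate early genes were lower in 16 of 19 (median -0.78), with Ier3 3.98-fold (3.90 to 4.06), Fosl2 2.87-fold and Fosb 2.75-fold lower, while Fosl1, Atf3 and Dusp2 were higher. RAS and MAPK output genes were lower in 17 of 22 (median -0.59), with Ccnd1, the gene of cyclin D1, 6.55-fold (6.33 to 6.78) and Phlda1 3.85-fold (3.74 to 3.96) lower. The percentile was below 0.5 in each of these 4 lists over all cells. Under some alternatives 3 of them lay inside the range of random lists drawn the same way: YAP and TAZ targets with the mean of per-cell CPM (median -0.33), RAS and MAPK output in cells A to D (-0.23) and TGF-beta targets in cells E to H (-0.48).

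Cholesterol and fatty acid synthesis genes were lower in 27 of 30 (median -1.02, below every random list), including the desaturase gene Scd2 (6.60-fold lower, 6.48 to 6.73), Hmgcs1 (4.47-fold, 4.34 to 4.61) and Sqle (3.15-fold, 3.08 to 3.22), while Sc5d had a log2 ratio of -0.05 and Pmvk, Stard4 and Acly had higher sums, of which Stard4 alone also had a higher mean log2(CPM + 1). NRF2 target genes were lower in 22 of 23 (median -1.05, below every random list), the exception being Gclc at 43.5 and 88.7 CPM, with the quinone reductase gene Nqo1 6.61-fold lower (6.22 to 7.02). The glutathione transferase genes Gstm1 and Gsta4 were 3.47-fold and 3.43-fold lower, and Gstm1 has close paralogs. Glycolysis and hypoxia genes were lower in 22 of 27 (median -1.01, below every random list), with lactate dehydrogenase A (Ldha) at 1908 and 428.4 CPM, 4.45-fold lower (4.43 to 4.48), Hk2 5.31-fold lower (5.03 to 5.59) and Pfkl 4.77-fold lower (4.63 to 4.91), while Slc2a3, Vegfa, Car9, Kdm3a and Mxi1 were higher. Oxidative phosphorylation genes were lower in 25 of 32 with a median of -0.24 (percentile 2.59), just inside the range of the random lists, and of -0.55 as a difference of mean log2(CPM + 1), including Ndufa13 (1.75-fold), Ndufa1 (1.65-fold) and Ndufa2 (1.602-fold lower), while Cox5a was at 479.2 and 478.0 CPM.

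The p53 target list was split. It had 15 of 25 members lower (median -0.47, percentile 1.03, but -0.24 in cells E to H, inside the range there), with Ccng1 5.51-fold (5.41 to 5.61) and Fas 2.66-fold (2.60 to 2.72) lower and the BH3-only gene Pmaip1 3.53-fold higher (3.37 to 3.70). Inflammation and NF-kB genes were lower in 15 of 21 (median -0.40, percentile 1.0), among them Lcn2, Cxcl5 and haptoglobin (Hp, 26.3-fold lower, 24.4 to 28.3), while Csf1 had a log2 ratio of -0.29. Heat shock genes (16 members, median 0.02), histones (10 members, -0.03), Wnt targets (7 members, -0.42) and epithelial adhesion and keratin genes (12 members, -0.40) lay inside the range of their random lists. Within them the small heat shock gene Cryab was 2.67-fold lower (2.64 to 2.70), Hspb8 2.25-fold lower, Hist1h2bc 1.93-fold lower, H2afx 1.58-fold higher, the glutamine synthetase gene Glul 4.95-fold higher (4.74 to 5.18) and the junction gene Jup 3.10-fold lower (2.98 to 3.22).

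Markers of differentiation state were examined because the series was made to follow dedifferentiation. Most mature hepatocyte genes were close to the detection floor in both infections. Only 6 of 45 markers reached 5 CPM in either infection, and albumin (Alb) stood at 0.37 CPM in Ad-GFP and 0.33 CPM in Ad-Cre. Of these 6 markers 4 were lower and 2 higher (median -0.77, percentile 7.17), inside the range of the random lists, but the median ran from -1.55 with the stricter cell filter to 1.37 with no filter on low values. The lower ones were Hp, Rbp4, Nr1h4, which had a higher mean log2(CPM + 1), and the transferrin gene Trf (453.1 and 169.6 CPM, 2.67-fold lower), and the higher ones were Cps1 (0.041 and 9.48 CPM) and Hpx (1.18 and 5.98 CPM). Hepatic progenitor and cholangiocyte markers were lower in 8 of 11 (median -1.31, percentile 0.15), among them Spp1, Cd24a (3.37-fold, 3.31 to 3.43) and Sox4 (2.85-fold, 2.71 to 3.01), while Epcam was at 0.00375 and 7.64 CPM and Krt7 and Muc1 also had higher sums, Muc1 with a lower mean log2(CPM + 1). Among cells with title letters A to D this median was -0.47, inside the range of its random lists. The mean per-cell CPM of Sox4 was 22.9 in Ad-GFP and 13.1 in Ad-Cre. Its difference of mean log2(CPM + 1) was -0.51 in cells A to D and -2.99 in cells E to H. Stem cell and self-renewal genes were lower in 10 of 13 (median -1.21, below every random list), with Cd34 10.8-fold lower (10.3 to 11.3), Ly6a, which encodes Sca-1, 5.28-fold lower (5.21 to 5.35) and the Notch target Hes1 4.53-fold lower (4.42 to 4.65), while Klf5, Bmi1 and Notch1 had higher sums, Notch1 with a lower mean log2(CPM + 1), and Myc was at 121.3 and 90.5 CPM. With no filter on low values the stem cell median was -0.15, inside its range. Fetal liver and oncofetal genes were higher in 8 of 12 (median 0.56, percentile 87.1, inside the range of the random lists), with Plagl1 1.84-fold higher (1.79 to 1.89) and Hmga2 4.08-fold lower (3.92 to 4.26). Peg3 was 1.85-fold lower over all cells and had the opposite sign among cells A to D (log2 ratio 0.10).

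Genes of stellate cells and fibroblasts were abundant in the control cells. Dcn stood at 3022 CPM in Ad-GFP and 1424 CPM in Ad-Cre, and all 10 measured markers of that list were lower in Ad-Cre (median -1.82, below every random list), including Acta2 at 4.52-fold (4.48 to 4.57) and Col1a2 at 3.65-fold. Of these 10 genes, 4 also belong to the matrix list. No lymphocyte or erythroid marker reached 5 CPM. Of Kupffer cell markers Csf1r (16.5 and 0.044 CPM) and Cd68 (7.35 and 1.25 CPM) did, and of endothelial markers Stab2 (0.21 and 7.37 CPM), too few for a median. With no filter on low values 9 Kupffer cell markers had a median of 4.05 at percentile 99.1, above the range of their random lists. Most of these 9 genes were under 5 CPM in both infections, and the 2 that were not, Csf1r and Cd68, were lower in Ad-Cre. With no filter 9 endothelial markers, also mostly under 5 CPM, had a median of 3.40, inside the range of their random lists.

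Spike-in RNA gave a measure of RNA content. The median cell had 49.96 gene counts per spike-in count in Ad-GFP (quartiles 41.6 and 70.1) and 67.1 in Ad-Cre (quartiles 39.3 and 88.5), a ratio of 1.34, while the ratio of the sums over cells was 1.02. A spike-in share above 10% was seen in 3 Ad-GFP and 7 Ad-Cre cells. A difference in the amount of spike-in between the infections would give the same ratio as a difference in RNA content. After thinning, the median cell had 6696 genes with a count in Ad-GFP (71 cells, quartiles 6248.5 and 7288.5) and 6968 in Ad-Cre (68 cells, quartiles 5709 and 7525.25). Before thinning the medians were 6922 and 6902.5.

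The infections lay apart on the main axis of the cells, with overlap. The median rank along the first diffusion component was 28.2% in Ad-GFP (quartiles 15.4% and 40.9%) and 74.8% in Ad-Cre (quartiles 62.2% and 87.4%), and the Ad-Cre cell lay further along in 93.4% of cell pairs. The middle of the axis was passed by 5 of 73 Ad-GFP and 70 of 76 Ad-Cre cells, and the 3 lowest ranks belonged to Ad-Cre cells. The far end was set by a lower mature hepatocyte score, which rested on 6 genes. Within each infection, cells further along had higher G1/S scores (Spearman rho across cells 0.43 in Ad-GFP and 0.57 in Ad-Cre) and lower extracellular matrix scores (-0.38 and -0.39). Interferon scores, higher in Ad-Cre, were lower in cells further along (-0.34 and -0.15), and inflammation (-0.51 and 0.02), immediate early (-0.38 and 0.21) and p53 target scores (-0.28 and 0.18) differed in sign between the infections. These describe the cells within 1 infection, from 30 measures examined in each infection. The axis was built from variable genes of these same cells with no list members left out, so such relations can partly restate how it was made. An axis made without the G1/S and G2/M genes had a rho of 0.99 with it over all cells. The position had a rho with the number of genes with a count of 0.15 in Ad-GFP and 0.27 in Ad-Cre, and with the spike-in share of -0.31 and -0.30.

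**Figure D3:**
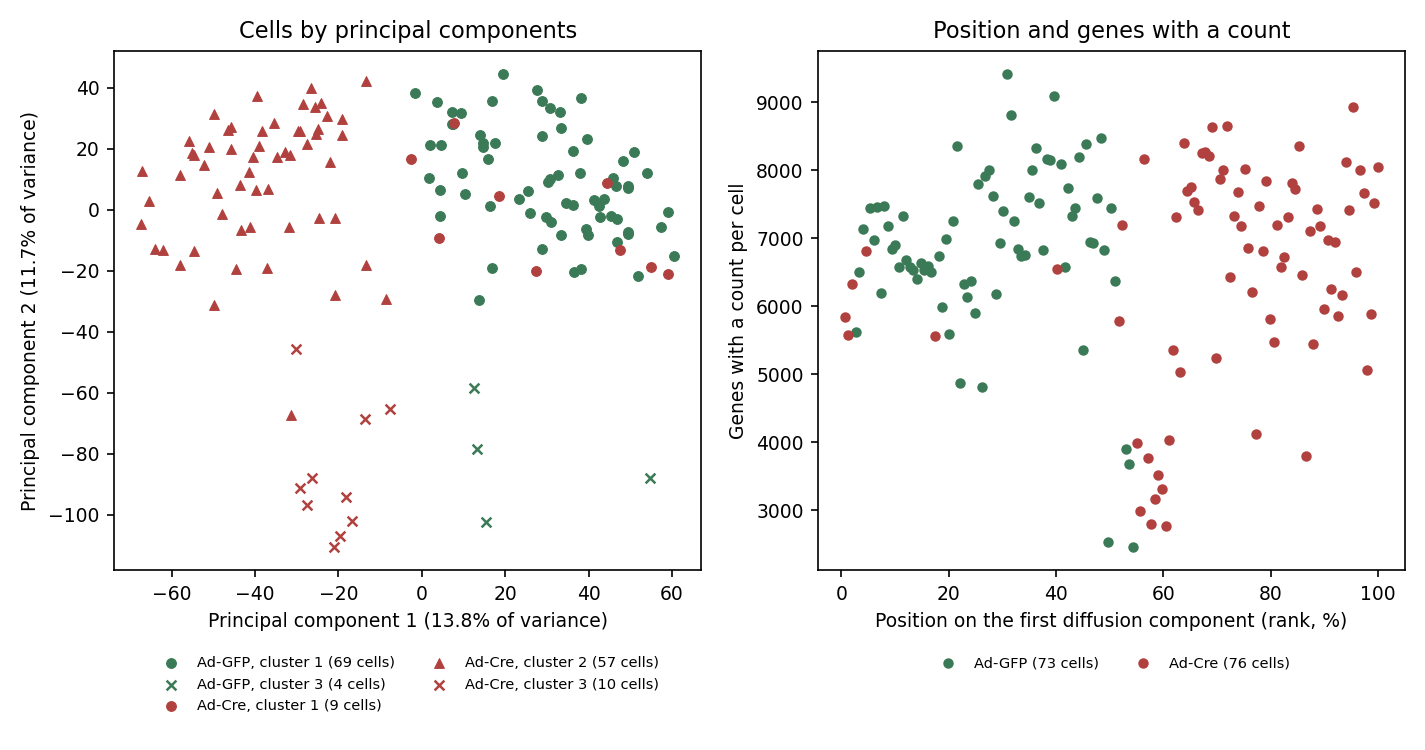
Left, 73 Ad-GFP and 76 Ad-Cre cells on principal components 1 (13.8% of variance) and 2 (11.7%), coloured by infection with a marker for each cluster. Right, rank along the first diffusion component (%) against genes with a count per cell, where the Ad-GFP median rank is 28.2% and the Ad-Cre median 74.8%.

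Clustering of the cells gave 3 groups (mean silhouette 0.25). The first held 69 Ad-GFP cells (94.5%, 86.6% to 98.5%) and 9 Ad-Cre cells (11.8%, 5.56% to 21.3%), a share of Ad-Cre cells that was 2.63% with 4 clusters. The second held 57 of 76 Ad-Cre cells (63.7% to 84.2%) and 0 Ad-GFP cells (upper limit 4.93%). The third held 4 Ad-GFP and 10 Ad-Cre cells with few genes detected, with a median of 3413 genes with a count and a median spike-in share of 20.1%. Their depth was mixed, from 126523 to 5695084 gene counts, with spike-in shares from 1.69% to 40.6%. The genes that separate the first 2 clusters are those that differ between the infections, so these shares are not a separate result, and none of the clusters was named as a cell type. When each infection was clustered alone, only the cells of the third cluster came apart, 4 of 73 in Ad-GFP and 10 of 76 in Ad-Cre, and the 9 Ad-Cre cells of the first cluster stayed with the other Ad-Cre cells. Cells were about equally alike within each infection. The median Pearson r between pairs of thinned cells was 0.533 in Ad-GFP (quartiles 0.507 and 0.560) and 0.529 in Ad-Cre, where the quartiles were wider (0.467 and 0.585).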

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

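Alternatives chosen after seeing the data were omission of cells with a spike-in share above 10%, cells with 6000 to 8000 genes with a count and omission of the cell with the most Arid1a in each infection, as was the comparison with random lists drawn under the same alternative. No paired analysis was possible because each infection was treated as 1 sample and the numbers in the titles only name cells. A list median was taken as moved when it shifted by more than the half-width of the range of its random lists, and a gene when it shifted by more than 1.5-fold. A reversal was counted only for lists outside their random range and genes at least 1.5-fold apart. That bound was set after the values were seen, because a first count of every sign change held mostly values near 0.

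Arid1a was lower in Ad-Cre in every alternative run. Its log2 ratio was -0.62 with the stricter cell filter, -0.30 with the mean of per-cell CPM, -1.44 as the difference of mean log2(CPM + 1), -0.67 with TMM factors, -0.66 with DESeq2 size factors, -0.53 with scaling to the spike-in total, -0.63 in cells A to D and -0.49 in cells E to H. It was -0.35 without the 5 deepest cells, -0.66 without cells of high spike-in share, -0.28 among cells with 6000 to 8000 genes and -0.65 without the highest cell of each infection. Leaving out the cell filter changed nothing, since no cell had failed it. The median of all genes was 0.11, and it was -0.089 as the difference of mean log2(CPM + 1), -0.013 with TMM factors and -0.0025 with DESeq2 size factors, shifts of -0.19, -0.12 and -0.11.

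Counting every sign change, 21 of 27 lists and 103 of 117 named genes other than Arid1a kept 1 direction throughout. The naming rule partly fixed the signs of genes, here and below. Under the bounds above, 15 of 374 list values moved and 0 reversed, and 169 of 1404 gene values moved and 2 reversed. These totals include alternatives that could not move or reverse a value, such as no cell filter. TMM, DESeq2 and spike-in scaling shifted all log2 ratios alike, by -0.12, -0.11 and 0.023, less than the bounds. Both reversals were Peg3, with a log2 ratio of 0.10 in cells A to D and 0.40 among cells with 6000 to 8000 genes. As differences of mean log2(CPM + 1) the extracellular matrix median was -2.80, cholesterol -1.42, NRF2 -1.92, G2/M 0.79 and oxidative phosphorylation -0.55. The lists that changed sign were heat shock, histones, Wnt targets, fetal liver, mature hepatocyte, and epithelial adhesion and keratins, whose median was 0.62 in cells A to D. The extracellular matrix median was -1.32 with no filter on low values and also at 20 CPM. With no filter the stem cell median was -0.15 and the mature hepatocyte median 1.37, and most of the 45 markers of that list lay under 5 CPM. Compared with random lists drawn under the same alternative, the 2 lists above their range stayed above and 8 of the 14 below stayed below in every alternative with a value. YAP and TAZ targets lay inside in 4 alternatives, p53 targets and RAS and MAPK output in 2 each, and TGF-beta targets, the progenitor and the stem cell list in 1 each. Of 11 lists inside, 5 stayed inside, while antigen presentation lay above in 6 alternatives, G2/M above in 4, oxidative phosphorylation below in 3, mature hepatocyte below in 2, and the integrated stress and epithelial lists outside in 1 each. The mature hepatocyte list had too few members for a value at 20 CPM and in cells E to H, as had the Wnt and epithelial lists at 20 CPM. The progenitor median was -0.47 in cells A to D. Among cells with 6000 to 8000 genes the interferon median was 0.75, the G2/M median 0.70 and the stellate median -2.58. The G2/M median in cells E to H was 0.093 from summed counts and 0.99 as a difference of mean log2(CPM + 1).

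The share of Ad-Cre cells grouped with most Ad-GFP cells was 2.63% with 4 clusters. The Ad-Cre to Ad-GFP ratio of gene counts per spike-in count was 1.02 from sums over cells. The median r between cells was 0.459 in Ad-GFP and 0.456 in Ad-Cre over genes with at least 20 CPM. The share of pairs with the Ad-Cre cell further along the axis lay between 92.1% and 94.1% with other gene numbers, without cell cycle genes, along the first principal component and without cells of high spike-in share, and was 94.2% among cells with 6000 to 8000 genes. The cause of these shifts was not tested. Depth limits folds that rest on few counts, such as that of Nrip3 with its 4 counts in Ad-GFP (948 to 8911).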

Other observations

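The gene families, the lower quartiles of the interferon and G1/S scores and the rho values with the number of genes taken out or in cells with 6000 to 8000 genes were tests chosen after results had been seen. Of 15 families formed from symbols, 14 had a value, and their percentiles partly restate the values that prompted them. Nucleoporin genes were higher in Ad-Cre in 19 of 19 measured members, with a median log2 ratio of 0.81 at percentile 99.8 of expression-matched random lists. Nup160 was at 75.3 and 268.4 CPM and Nup107 at 73.7 and 187.2 CPM in Ad-GFP and Ad-Cre. Kinetochore genes with Cenp symbols were higher in 16 of 18 (median 1.27, above every random list), with Cenpl at 10.6 and 69.5 CPM, while Cenpa, the centromeric histone gene, was at 258.2 and 142.7 CPM. Of the Cenp genes, 3 belong to the fixed lists. Genes with Zfp symbols, mostly zinc finger proteins, were higher in 208 of 270 (median 0.63, above every random list), and DNA repair genes in 21 of 29 (median 0.57, percentile 98.1).

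Genes with Tuba, Tubb and Tubg symbols, which include tubulin complex genes, were lower in 10 of 16 (median -0.60, percentile 0.34), with Tubb3 at 41.6 and 3.78 CPM and Tuba1a at 740.6 and 224.1 CPM. Matrix metalloprotease genes were lower in 9 of 10 (median -1.44, percentile 0.01), 2 of the 10 in the fixed lists and Mmp10 and Mmp13 among the 12 lowest genes, with Mmp3 at 1053 and 195.4 CPM. Chemokine genes were lower in 10 of 14 (median -1.29, below every random list, but -0.57 and inside the range as a difference of mean log2(CPM + 1)), 7 of the 14 in the fixed lists, and aldehyde and aldo-keto enzyme genes in 16 of 19 (median -0.86, percentile 0.02). Ribosomal protein genes had a median of -0.13 and, as a difference of mean log2(CPM + 1), -0.57, each just below its range. Mitochondrial ribosome (0.29 and -0.14), proteasome (-0.11 and -0.58), solute carrier (0.06 and -0.13), tRNA synthetase (0.52 and 0.30) and kinesin genes (0.22 and 0.08) lay inside their ranges on both scales.

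The infections lay apart on the main axis. The number of genes detected did not account for this, since among 49 Ad-GFP and 37 Ad-Cre cells with 6000 to 8000 genes the Ad-Cre cell lay further along in 94.2% of pairs. With the trend on length and GC content removed from the gene ratios, the extracellular matrix median was -1.57, below its random lists (-0.28 to 0.50). Such a bias therefore did not account for the lower matrix list. The axis was not recomputed on corrected values, so its part in the positions of the cells remains open. If the Arid1a RNA left in a cell set its position, Ad-Cre cells with less would lie further along, but the rho of Arid1a with position was 0.43 in Ad-Cre cells, 0.38 with the number of genes taken out, and -0.08 in Ad-GFP cells. These counts include exons that a deletion leaves in place, and 26 of 76 Ad-Cre cells had none. They cannot decide whether the amount of intact Arid1a in a cell set its position. Loss of Arid1a, Cre itself and the virus dose cannot be told apart from each other or from a batch that follows the title prefix, since each prefix holds 1 infection.

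Interferon genes were higher in Ad-Cre, with Ifnb1 counts in few cells. A few very high cells did not account for this, since in thinned cells the lower quartile of the score was higher in Ad-Cre by 0.391, about as much as the median (0.383). Nor did reads shared between paralogs, since the 20 members left without families of like symbols, Irf and Stat genes kept, had a median of 1.13, above their random lists (up to 0.49). An event shared cell by cell with the lower matrix genes would give a negative rho between both scores in Ad-Cre cells, where it was 0.48, 0.36 with the number of genes taken out, and 0.27 and 0.22 in the 37 cells with 6000 to 8000 genes, which leaves an event present in all Ad-Cre cells open. Secreted interferon, virus dose, loss of Arid1a, Cre itself and a batch that follows the title prefix also remain open.

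G1/S genes were higher in Ad-Cre. Ad-Cre cells did not have more genes detected before thinning (median 6902.5 against 6922 in Ad-GFP), though they did after it (6968 against 6696). Among cells with 6000 to 8000 genes the list median was 1.29, above its random lists (up to 0.41). The number of genes detected therefore did not account for the higher list. In thinned cells the lower quartile of the score in Ad-Cre, 0.073, lay above the median in Ad-GFP, -0.26. A larger share of cells in S phase and a higher level of these genes in most cells cannot be told apart by this value, since a share large enough also lifts the lower quartile. Loss of Arid1a, Cre itself, virus dose and a batch that follows the title prefix remain open too.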
